A study of Drosophila melanogaster with 4 samples.

How the data were processed

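The series is a ChIP-seq study of dRING in Oregon-R embryos aged 14 to 16 h, with 2 ChIP libraries and 2 input libraries. Per the labels' protocols, embryos no older than 16 h were fixed with 1.8% formaldehyde, and chromatin was incubated with the antibody for 15 hours and collected on beads. Each input library is named in the labels as the input of 1 ChIP library. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the replicates came from separate embryo collections, so the spread between them may be technical.

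Bowtie 0.12.7 is named in the submitters' processing notes, and the genome build is FlyBase release 5, per the file headers. The region caller, its threshold and the way the replicates were combined for the series list are not given in the sources used here. Both replicate lists start at a length of 1301 bp and the series list at 1001 bp, so the lists were not made with the same minimum length. The deposited score of each interval is the authors' own value with no stated scale, and it was used to rank, filter and describe intervals and to compare mean scores between sets of intervals within a list. Scores of overlapping clusters were also set side by side between the replicate lists, as differences and as a mean ± SD. Each list carries its own scores, and how they compare between lists is not given in the sources used here, so such differences describe the lists and are no measure of a difference in binding. Per the labels, the inputs served in the making of each replicate list, and no separate input values were analysed here. The files give no read counts, so depth and its precision are unknown, and the exact binomial (Clopper-Pearson) 95% intervals of shares of clusters cover counting error only.

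The lists were read with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9. Positions are 1-based. The main analysis kept the arms 2L, 2R, 3L, 3R, 4 and X, and left out the heterochromatic and unplaced sequences, which are described at the end. Lists were compared by overlap of at least 1 bp. Overlap expected by position alone was taken from 1000 circular shifts of one list within each arm, with a fixed seed and a one-sided p. Scores were compared across overlapping pairs by Spearman's rho with 100000 permutations. Of 2 such correlations computed, the other, of length and score in regions seen in both replicates, gave rho = 0.43 (two-sided permutation test, p = 1e-05), and Benjamini-Hochberg adjustment over the 2 left both p-values at 1e-05. A region of the series list was called seen in both replicates where a cluster of each overlapped it. With 2 replicates no test over libraries was made, and tests over clusters, regions or domains treat places in the genome as units.

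The overlap and shift procedure was tested on simulated data made from the 3458 replicate 1 clusters. In each of 20 simulated lists per setting the count equalled a direct pairwise count. With 30% or 60% of the clusters planted as shared, all 20 lists had p under 0.05. With none planted, 1 of 20 did. Overlap was found for 37.3% of the clusters with 30% planted and for 62.8% with 60%. Planted clusters were moved by less than the length of any cluster, so their detection was close to certain. The others were placed at random, so lists that group along the arms were not tested.

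The rule for named regions was fixed before the data were examined: the 10 highest scores and the 10 longest among regions seen in both replicates. The alternatives were also fixed then, namely the clusters above the median score of each list, 50% overlap, merging of clusters less than 1 kb apart, random placement, all sequences, each replicate alone, cluster length in place of score for the correlation and covered bases in place of clusters for the arms. Domains (regions seen in both replicates less than 10 kb apart), their alternatives, the contrast of long and shorter regions, the score of X against other arms and the bootstrap over 1 Mb blocks (2000 draws) were chosen after seeing the data. Domains, the unshared cluster, single clusters inside domains and regions of chromosome 4 named in the text were also chosen after their values were seen. The design had also planned tests of 14 gene lists, of transcription start windows and of sequence motifs. These were not made, because the only gene table at hand is of release 6, the files are in release 5, and coordinates were not converted between builds. Genes were therefore neither named nor tested.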

Results

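Binding of dRING was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type Oregon-R embryos of Drosophila melanogaster aged 14 to 16 h. dRING, the product of Sex combs extra, is a RING-finger subunit of Polycomb repressive complex 1 and the enzyme that ubiquitinates histone H2A at Polycomb targets. The series held 2 ChIP libraries made with the same antibody and 2 matched input libraries, 1 for each ChIP library. The deposited lists gave enriched intervals, called clusters here for a single library and regions for the list of the whole series, with the authors' score for each. On the 6 chromosome arms (120.4 Mb in FlyBase release 5), replicate 1 held 3458 clusters covering 9.12 Mb (7.57%) and replicate 2 held 3048 clusters covering 7.15 Mb (5.94%). The series list held 7386 regions covering 16.4 Mb (13.6%). The lists give no read counts, so the sequencing depth behind a cluster is unknown. Regions are named by position, because gene annotation of release 5 was not used here.

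The first comparison asked how far the 2 ChIP libraries marked the same places. Of the replicate 1 clusters, 2188 of 3458 (63.3%, exact 95% interval 61.6 to 64.9%) overlapped a replicate 2 cluster by at least 1 bp. Of the replicate 2 clusters, 2341 of 3048 (76.8%, 75.3 to 78.3%) overlapped a replicate 1 cluster. Circular shifts of one list along each arm gave 11.8% and 13.5% on average, and at most 16.7% and 20.5% in 1000 shifts. Both shares lay above every shift (one-sided test by circular shifts, p = 0.001, the smallest these can give; n = 3458 and n = 3048 clusters). The replicates shared 5.61 Mb, which was 61.6% of the bases of replicate 1, 78.4% of those of replicate 2 and 10.2 times the mean of the shifts. The intervals treat clusters as independent and cover counting error only.

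Clusters with high scores were nearly all found in both libraries, while those with lower scores were shared less often. In the highest decile by score, 342 of 345 replicate 1 clusters (99.1%, 97.5 to 99.8%) and 304 of 304 replicate 2 clusters (100%, lower bound 98.8%) overlapped the other list. In decile 4 of replicate 1, with scores from 0.51 to 0.55, the share was 39.0% (33.8 to 44.4%), the lowest of all deciles. The share did not fall steadily with score: in the lowest decile it was 56.6% (51.2 to 61.9%) in replicate 1 and 54.8% (49.0 to 60.4%) in replicate 2. Shared clusters of replicate 1 had a mean score of 0.90 and unshared ones 0.54, and in replicate 2 the means were 1.08 and 0.59 (two-sided permutation tests over clusters with 100000 resamples, p = 1e-05 for both, the smallest these can give). Shared clusters were also longer, with a median of 2163 bp against 1573 bp in replicate 1 and 2139 bp against 1561 bp in replicate 2. All 73 replicate 1 clusters and all 9 replicate 2 clusters of 10 kb or longer were shared. Longer clusters meet the other list more often by position alone, and no shifts were made by length. The unshared cluster with the highest score lay on 2R from 10776737 to 10778428 in replicate 1, with a score of 1.70.

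**Figure D1:**
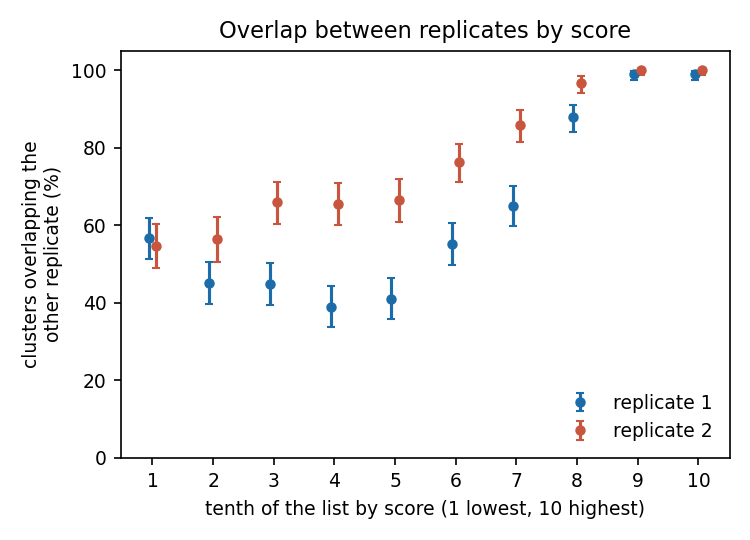
Share of clusters overlapping the other replicate (y axis, percent) in each decile of a list by score (x axis, 1 lowest to 10 highest). Points are shares of replicate 1 (blue) and replicate 2 (red) and bars are exact 95% binomial intervals; the share reaches 99.1% and 100% in the highest decile.

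The scores of shared clusters rose together, and replicate 2 gave the higher score for most of them. Across 2188 pairs of overlapping clusters, Spearman's rho was 0.83 and Pearson's r 0.92 (two-sided permutation test of rho over pairs, p = 1e-05). Each replicate 1 cluster was paired with the replicate 2 cluster that overlapped it most, so some replicate 2 clusters entered more than once. These pairs are places in the genome and not independent replicates. The replicate 2 score was higher in 1665 pairs (76.1%), with a median difference of 0.15 (quartiles 0.004 and 0.34). The score has no stated scale. Of the 6 scores above 0.7 that recur in at least 4 regions of the series list, 5 gave whole multiples of a single step to within 0.001 when 2 was raised to the score, as a base-2 logarithm of a ratio of counts would. The scale was not otherwise established, and scores are compared as differences and not as folds.

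**Figure D2:**
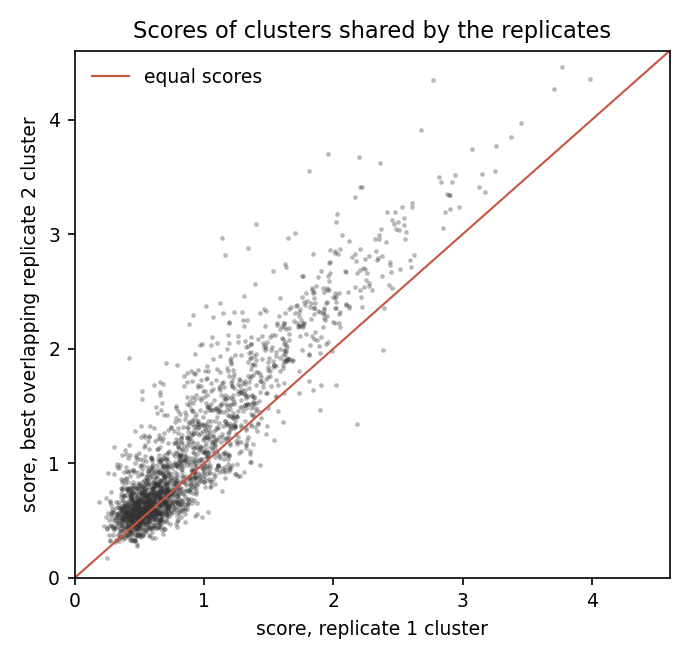
Authors' score of each replicate 1 cluster (x axis) and of the replicate 2 cluster that overlaps it most (y axis), for 2188 pairs on the chromosome arms. The red line marks equal scores, and 76.1% of the pairs lie above it.

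The series list was set against the 2 libraries to find the regions seen in both. Clusters of both replicates overlapped 2100 of the 7386 regions (28.4%), and these held 50.0% of the listed bases. A further 1131 regions were overlapped in replicate 1 alone, 642 in replicate 2 alone and 3513 (47.6%) in neither. Median scores were 0.68 (95% bootstrap interval 0.65 to 0.71) for regions seen in both, 0.38 (0.375 to 0.384) for those seen in a single replicate and 0.40 (0.399 to 0.404) for those seen in neither. All 106 regions of 10 kb or longer were seen in both replicates, though long regions meet clusters more often by position alone. Of the regions seen in neither, 2030 (57.8%) were shorter than the shortest cluster of either replicate, which was 1301 bp, while the shortest region of the series list was 1001 bp.

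The 10 regions with the highest scores among those seen in both replicates were narrow sites of 2.52 to 5.51 kb. The highest lay on 2R from 2548526 to 2552509, with a series score of 4.07 and a mean replicate score of 4.11 ± 0.49 (SD, n = 2). It was followed by 3R from 5932986 to 5936645 (3.99 ± 0.40, SD, n = 2) and 3R from 9841393 to 9846231 (4.17 ± 0.26, SD, n = 2). On 2R, the region from 18447828 to 18450503 had 3.61 ± 0.33 and the region from 9916581 to 9922092 had 3.29 ± 0.87 (SD, n = 2 for each). The region of 3L from 21231956 to 21234559 had 3.41 ± 0.48 (SD, n = 2). A group of 3 sites stood within 54.4 kb of 2R, at 6106018 to 6108532, 6111629 to 6114144 and 6157600 to 6160391, with mean scores of 3.40 ± 0.22, 3.34 ± 0.26 and 3.51 ± 0.36 (SD, n = 2 for each). The last of the 10 was on 3R from 19170758 to 19173833 (3.71 ± 0.37, SD, n = 2). Each of the 10 was a single cluster in both libraries, and replicate 2 gave the higher score at each, by 0.31 to 1.23.

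The 10 longest regions seen in both replicates spanned 27.5 to 95.6 kb, had series scores of 1.06 to 1.88, and included none of the 10 with the highest scores. The longest, on 2R from 8835830 to 8931418, was 99.9% covered by 1 cluster in replicate 1 and 95.3% covered by 2 clusters in replicate 2. Where a replicate had several clusters in a region, only its highest score entered the mean, here 1.82 ± 0.12 (SD, n = 2). The replicate 2 clusters here had scores of 1.68 over 72.2 kb and 1.73 over 19.0 kb. The region of X from 2012284 to 2042816 was also nearly filled in both, at 97.2% and 94.6%. The mean of its highest cluster scores was 2.00 ± 0.02 (SD, n = 2), and its series score was 1.88. The other 8 were covered from 89.4 to 99.7% in replicate 1 but from 42.1 to 72.7% in replicate 2. Of these, 3 lay close together on 3R, from 12661259 to 12688784, from 12688922 to 12729749 and from 12753765 to 12802847. A pair of further 3R regions ran from 652030 to 699814 and from 17250899 to 17279395. The remaining 3 ran on 3L from 8992903 to 9040595, on 3L from 12659798 to 12699696 and on 2L from 3817239 to 3849116. Replicate 1 had 20 clusters over the 10 regions and replicate 2 had 50.

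Coverage by the replicates was also compared over all long regions, a contrast chosen after the 10 longest had been seen and including them. In the 106 regions of 10 kb or longer, replicate 1 clusters covered 91.3% of a region on average and replicate 2 clusters 56.4%, a difference of 34.8 ± 16.8 percentage points (SD over regions), and replicate 1 covered more in 102 of the 106. In the 1994 shorter regions the means were 85.6% and 82.1%, a difference of 3.51 ± 17.5 points. No p-value is given for the contrast of the 2 differences, since it was chosen after its largest members had been seen. No cluster was shorter than 1301 bp, which limits how finely a short region can be covered. Of the 1994 shorter regions, 1883 held 1 cluster of replicate 1 and 1891 held 1 of replicate 2, against 51 and 21 of the 106. The spread of the difference was similar in both sets, which does not remove this limit. Long regions were picked by length in the series list, whose relation to the replicate lists is not given. The contrast is therefore not independent of that choice. The median series score rose with length, from 0.35 under 2 kb to 0.67 from 2 to 5 kb, 0.85 from 5 to 10 kb and 1.07 for 10 kb or longer (Spearman's rho of length and score across the 2100 regions 0.43, two-sided permutation test, p = 1e-05). The highest scores were nevertheless at regions of intermediate length: a score of 2 or more occurred in 126 of 1576 regions from 2 to 5 kb, 18 of 237 from 5 to 10 kb, 0 of 181 under 2 kb and 0 of 106 of 10 kb or longer. In the region of 3R from 12661259 to 12688784, with a series score of 1.20, the highest cluster scores were 1.29 in replicate 1 and 2.32 in replicate 2.

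**Figure D3:**
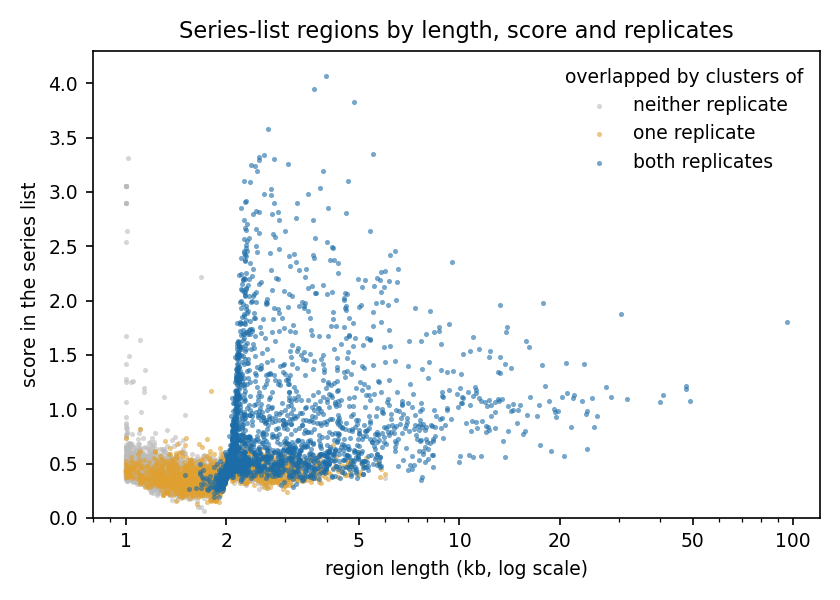
Length (x axis, kb, log scale) and authors' score (y axis) of the 7386 series-list regions on the chromosome arms, coloured by whether clusters of both replicates, a single replicate or neither overlap them. Regions of 10 kb or longer are all seen in both replicates and none of them reaches a score of 2.

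Regions seen in both replicates were clustered along the arms. When regions less than 10 kb apart were joined, the 2100 regions formed 1427 domains, where random placement of the same regions gave 1640 on average and at least 1583 in 1000 draws (one-sided test by random placement, n = 2100 regions, p = 0.001, the smallest these can give). Regions that nearly adjoin, such as 3R from 12661259 to 12688784 and from 12688922 to 12729749, may be pieces of a single enriched stretch. Random placement does not keep such neighbours together, so the test cannot tell this splitting from grouping of separate sites. This definition of a domain was chosen after seeing the data. The 10 domains with the most covered bases held 10.97% of the bases of all regions seen in both replicates, counted over the full length of each region. The largest, on 3R from 12521907 to 12810523, spanned 289 kb and held 14 regions covering 243 kb. Within it replicate 1 covered 85.1% of the span in 29 clusters and replicate 2 covered 44.9% in 39 clusters. The strongest replicate 2 cluster there, from 12670993 to 12678369, had a score of 2.32. The highest replicate 1 score was 1.34, at a different place, from 12650011 to 12659903. Each list carries its own scores, so this is no measure of a difference in binding.

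The next domain was on 3L from 12557255 to 12703056, with 126 kb covered in 11 regions. Another domain, on 3R from 2706479 to 2840078, held 111 kb in 10 regions, and its strongest replicate 2 cluster, from 2823720 to 2828314, had a score of 3.01. The domain on 2R from 7352792 to 7454847 held 69.2 kb in 8 regions. On X, the domain from 17632077 to 17700090 held 50.1 kb in 8 regions. The domain on 3R from 12031197 to 12085478 combined wide cover in both replicates (83.7% and 79.6% of its span) with high scores, the strongest cluster having 2.60 in replicate 1 and 3.23 in replicate 2. Replicate 1 covered more of the span than replicate 2 in all 10 domains, and in 7 of them by over 1.5 times. Replicate 2 had more clusters than replicate 1 in 7 of the 10. The domain on 3R from 12521907 to 12810523 remained the largest in place with gaps of 5 or 20 kb and with either replicate alone, with 164 to 260 kb covered.

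**Figure D4:**
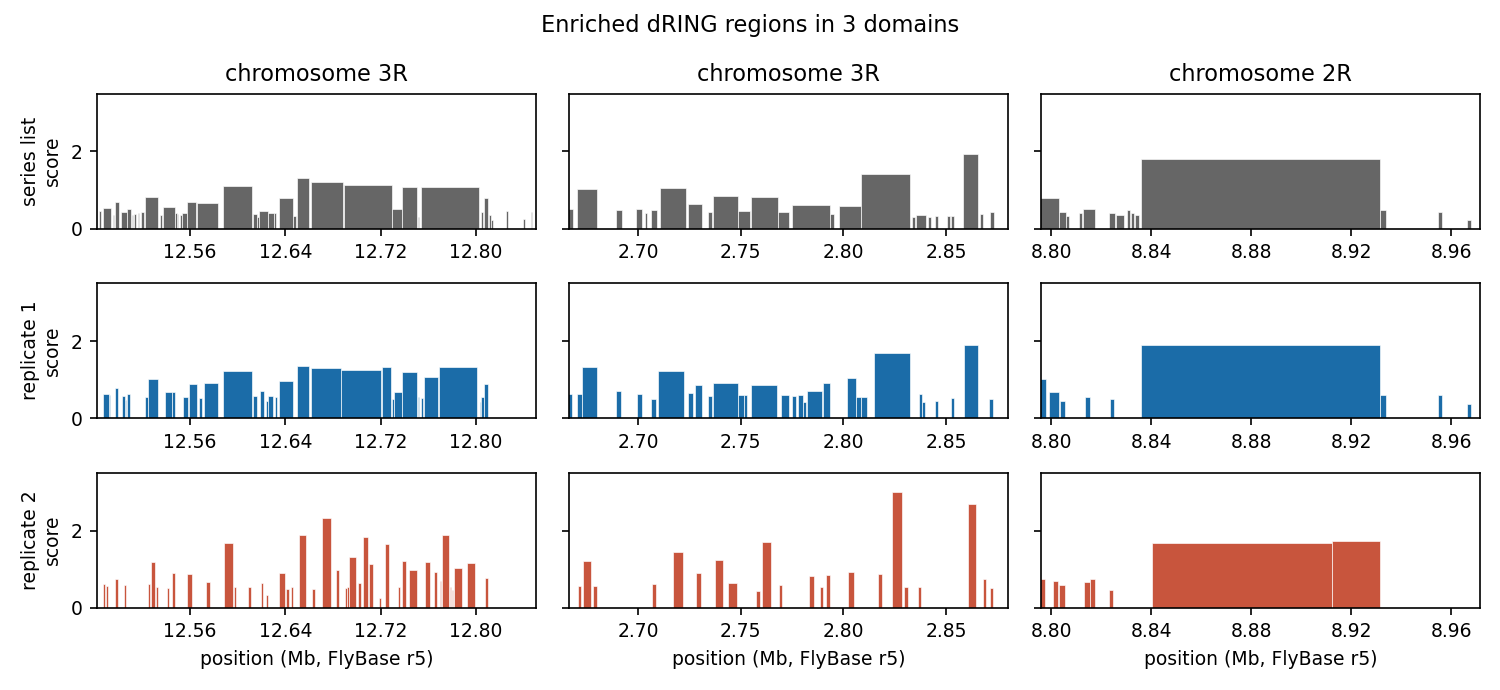
Position (x axis, Mb in FlyBase release 5) and score (y axis) of every listed interval in 3 domains, with the series list in grey, replicate 1 in blue and replicate 2 in red; each bar is as wide as its interval. In both 3R domains replicate 2 covers less of the span than replicate 1. Replicate 2 has 39 clusters against 29 in the domain from 12521907, and 16 against 21 in the domain from 2706479. The 95.6 kb region of 2R is filled in both.

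Clusters per arm were set against the length of each arm. X makes up 18.6% of the arm length and held 744 clusters (21.5%, exact 95% interval 20.2 to 22.9%) in replicate 1, 702 (23.0%, 21.5 to 24.6%) in replicate 2 and 498 of the 2100 regions seen in both (23.7%, 21.9 to 25.6%). Arm 3R, with 23.2% of the length, held 25.7% of the clusters in replicate 1 and 25.03% in replicate 2. Arms 2L (19.1% of the length) and 3L (20.4%) held 17.3% and 17.8% in replicate 1, and 16.1% and 17.5% in replicate 2. Chromosome 4, with 1.12% of the length, held 34 clusters in replicate 1 (0.98%, 0.68 to 1.37%) and 18 in replicate 2 (0.59%, 0.35 to 0.93%). Because clusters group along the arms, intervals were also drawn by bootstrap over 1 Mb blocks. For X these were 18.3 to 24.6% in replicate 1, which includes its share of the length, 19.8 to 26.3% in replicate 2 and 20.6 to 26.7% for regions seen in both. The block intervals for 3R included its share of the length in both replicates, and those of 2L and 3L did so in replicate 1 (14.2 to 20.4% and 14.9 to 20.6%) but lay below it in replicate 2 (13.3 to 19.07% and 14.9 to 20.2%). In replicate 1 the block interval of each of the 6 arms included its share of the length.

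**Figure D5:**
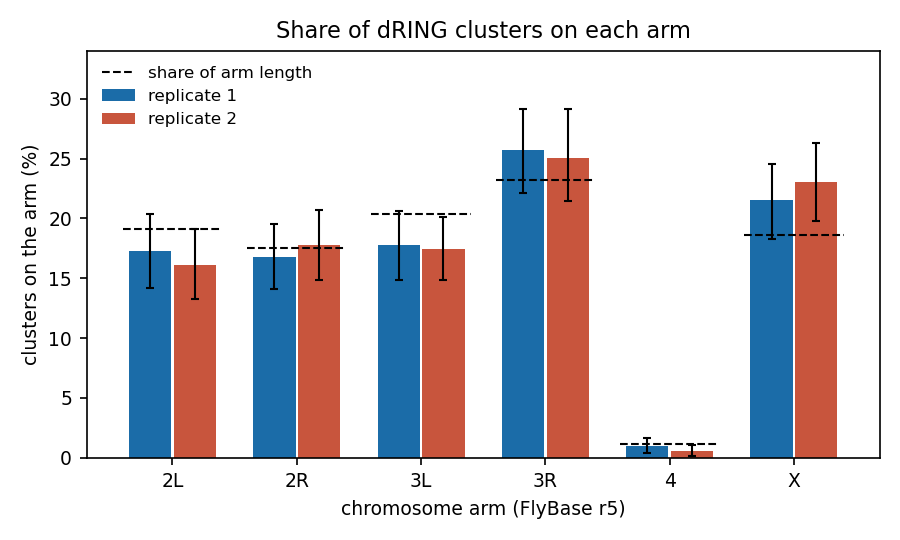
Share of clusters on each chromosome arm (y axis, percent of the clusters on all arms) in replicate 1 (blue) and replicate 2 (red), with 95% bootstrap intervals over 1 Mb blocks; dashed lines mark the arm's share of the total length. On X the bars stand at 21.5% and 23.0% against a length share of 18.6%.

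Regions on X also had higher scores than those on the arms of chromosomes 2 and 3. Among regions seen in both replicates the mean series score was 1.05 for 498 regions on X and 0.86 for 1587 regions on those arms, a difference of 0.20 (two-sided permutation test over regions, p = 1e-05, the smallest it can give). This test treats regions as independent, although 1075 of the 2100 lay in domains of 2 or more. No block interval was made for the difference, so the p-value may overstate the evidence. The median length was 2629 bp on X and 2575 bp on the other arms. The lowest decile of the scores ended at 0.47 on X and 0.39 elsewhere, and the highest decile began at 1.98 and 1.65.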

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

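The comparisons of recurring scores and of regions of like length below were chosen only after the data had been seen, and the overlap with the replicates against regions of matched score was written before its result was seen.

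Outside the main arms, the series list held 79 regions on heterochromatic and unplaced sequences, a signal in sequences that the main comparisons leave out. Of the 79, 53 lay on the unplaced sequence U. Their median series score, over all 79, was 1.42, against 0.42 on the arms, and 24 had a score of 2 or more. In replicate 1 the median was 0.98 against 0.60 on the arms (15 clusters, 2 with a score of 2 or more). In replicate 2 it was 0.57 against 0.71 (13 clusters, 3 with such a score). No interval or test was made for these few clusters, so no direction is drawn from them. Sites bound alike in both libraries cannot be told apart from other explanations: 5.06% of the 79 were seen in both replicates (exact 95% interval 1.40 to 12.5%), against 79.0% of arm regions of matched score, but 61 of the 79 were shorter than any replicate cluster, a length at which 0 of 2213 arm regions were seen in both either. Of the 18 longer ones 4 were seen in both (22.2%, 6.41 to 47.6%), against 60.8% of arm regions of such length matched on score, 21.7% matched on length and 34.7% matched on both. Ratios of very few reads stay open too. A score that recurred exactly in the list was held by 53.2% of the 79 and 36.5% of the arm regions. Among regions shorter than any replicate cluster these shares were 60.7% (47.3 to 72.9%) and 65.7% (63.7 to 67.7%), respectively. Such regions were not matched on score, so the comparison cannot speak to the high scores alone. The highest scores on 2LHet and YHet (2.54), 2RHet (2.90), and 3LHet and U (3.43) each recurred in the list. Those on 3RHet and XHet were lower, at 0.99 and 0.31. No biological explanation was tested.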

How the results depend on the processing

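Of 42 recomputed values, 39 kept their direction and their side of the threshold, or stayed within 1.5 times (counts) or the exact interval (shares); the 8 for domains were chosen after seeing the data. Overlap ranged from 59.7 to 67.6% of replicate 1 clusters and from 75.2 to 80.6% of replicate 2 clusters, shared bases from 10.2 to 15.6 times the mean of the shifts or random placements, and rho of the scores from 0.83 to 0.84; with cluster length in place of score, rho was 0.70. The count of 2100 regions seen in both replicates fell to 1131 with the clusters above the median score of each list, since fewer clusters were used, and ranged from 2742 to 3231 with a single replicate required (replicate 2 and replicate 1, respectively). The number of domains, 1427, ranged from 1139 with gaps of 20 kb to 1632 with 5 kb, and from 1747 to 1785 with a single replicate required. Counted by covered bases, 3R held 27.8% in replicate 1 instead of 25.7%, outside the interval of the share of clusters. Replicate 1 clusters on 3R were thus longer on average than those over all arms, and why they were was not tested. No paired analysis was possible because the input libraries, the only other group that shares the replicate numbers, have no values of their own analysed here. The gene list, start window, Hox complex and sequence alternatives were not run, since they need an annotation or genome of release 5. Unknown depth limits what an unshared cluster can show: absence from a list does not by itself show absence of binding.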

Other observations

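The test of minimum length and the block intervals of shares of regions were chosen after the data had been seen, and the other tests were written before their results were seen.

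The small chromosome 4 carried 15 regions seen in both replicates. The longest were 4 from 1004631 to 1018134 and 4 from 519321 to 531722, and the highest series score was 1.15, at 4 from 719117 to 728002. The latter had scores of 1.44 in replicate 1 and 1.39 in replicate 2. Among all regions seen in both replicates, 816 (38.9%) measured 2 to 2.5 kb.

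The excess of regions on X was weighed against 2 technical explanations. Unreplicated calls alone do not account for it. Without selection by score, X held 23.7% of the regions seen in both replicates (20.6 to 26.7% by 1 Mb blocks), above its 18.6% of the length. Weak calls stay open. Of the regions seen in both replicates with scores above the median, X held 29.1% (exact interval 26.4 to 32.0%, 24.9 to 33.3% by blocks). Regions on X broken into more pieces cannot be told apart from a wider bound area, because X held 21.3% of the covered bases and the block interval, 18.2 to 24.6%, includes its share of the length. The same score cut served all arms, and the higher scores on X raise the share of 29.1%. That share therefore cannot tell strong calls on X from weak calls with raised scores. A score scale that differs between X and the autosomes stays open, and neither it nor a biological explanation was tested.

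The 3513 series-list regions seen in neither replicate were weighed in the same way. A shorter minimum length in the series list is a candidate explanation for part of them: 57.8% (56.1 to 59.4%) were shorter than any replicate cluster, against 10.3% (8.94 to 11.8%) of those seen in a single replicate. Weaker sites gained by combining the replicates did not show as lower scores, since the median was 0.022 higher than for regions seen in a single replicate (95% bootstrap interval 0.016 to 0.028). Among regions from 1301 bp to 2 kb the difference was 0.0051 (-0.0004 to 0.014), which leaves that explanation open at matched length. Calls scattered without relation to the replicated regions do not account for all of them, since 28.7% lay within 5 kb of a region seen in both replicates, against 22.5% on average and at most 25.7% in 1000 circular shifts.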
